A study of Homo sapiens with 12 samples.

How the data were processed

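Messenger RNA was sequenced from RPE-1, an established human cell line from retinal pigment epithelium, in 12 libraries of 4 groups with 3 libraries each. Per the labels, the cells were kept for 24 h without fetal calf serum (FCS) and glucose. The starved group was taken then. The remaining groups received 10% FCS and 5 g/l glucose for 4 h with the solvent DMSO, with 100 µM dimethyl amiloride (DMA) or with 10 µM C646. DMA inhibits Na+/H+ exchangers, and C646 inhibits the histone acetyltransferases p300 and CBP. The labels number the libraries of each group from 1 to 3 and do not say whether these are separate cultures, so every p-value measures only the spread between these samples.

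The submitters' notes name Trimmomatic 0.36, STAR 2.7.0e and the genome build GRCh38.p10. The deposited tables give for each transcript, per the file headers, expected counts (estimated reads), TPM (length-corrected transcript shares scaled to a total of 1000000) and an effective length, a value of another kind than expression. The deposited expected counts are fractional and sum to a different total in each library. The deposited TPM sum to the same total in each library. The quantification program, its annotation and its strand setting are not given in the sources used here. The design had assumed raw read counts. The expected counts were therefore summed over the transcripts of each gene in GENCODE 29 and rounded before testing. Of 182164 transcripts, 92 were spike-in control sequences, whose identity and amount the labels do not state. Another 264 matched no GENCODE 29 transcript and were left out, with 0.0923% to 0.146% of a library's counts. The remaining 181808 transcripts belong to 43481 genes. TPM served only to check the tables and to weight the effective lengths of a gene's transcripts, which were used only for 1 alternative.

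The libraries hold 14910516 to 28968510 expected counts. A limit of 3 reads corresponds to 0.105 to 0.203 CPM (counts scaled to a library total of 1000000), which covers counting error only. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15263 genes. They were scaled with the trimmed mean of M-values (TMM) and tested with edgeR 4.0.16 by robust quasi-likelihood F-tests, with all 12 libraries in 1 fit. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. SE of log2 fold changes come from the same fits. Group levels are mean CPM ± SD, n = 3. There were 6 comparisons between pairs of groups.

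Gene lists (30, with 622 memberships, of which 589 were tested and 33 were not, and 580 distinct genes tested) were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives except 3 added later. Each list was tested against all other genes with limma 3.58.1 camera on log2 CPM with a prior count of 2. The preset inter-gene correlation was 0.01, and an estimated correlation was an alternative. Camera p-values were adjusted over the 30 lists of a comparison. List members were also counted with p-values adjusted over the list alone. Of the genes tested, 9 are in more than 1 list.

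Named genes are the 6 largest changes in each direction (4 for DMA against C646) among genes past the threshold with a symbol, a mean log2 CPM of at least 2 and no overlap between the libraries of the groups, a fixed panel of 16 genes, and up to 2 members in each direction of each list. Other genes are named only where said. A gene is called uncertain where over 20% of its 31-base sequences occur in other genes or over 20% of its exons overlap another gene on either strand. This held for 29 of 202 genes checked.

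Alternatives chosen with the design were DESeq2 1.42.0 (Wald test), DESeq2 size factors, no filter, a stricter filter (1 CPM in each library of a group), only the compared groups, the replicate number as a block, a log2 fold change of at least 1 and leaving out each library. Scaling to the spike-in counts, a transcript length offset and the block without solvent library 1 were added after seeing the data. Spike-in scaling also changed the SE and p-values of single genes, so its counts of calls are not directly comparable with those under TMM. The numbers pair the libraries where each library's deviation from its group mean resembles the deviation under its own number in the other group most, with a correlation across genes above 0.1. Own-number correlations were 0.28 to 0.48 between the 3 stimulated groups and 0.13 to 0.36 for the inhibitor groups with starved cells. For solvent with starved cells they were 0.0957, 0.33 and 0.18. There the own number was also the closest for each solvent library, but 0.0957 misses the limit, so the pairing does not hold by this rule. Since the inhibitor groups pair with both, a pairing of solvent with starved cells is not excluded. For comparisons that share a control group, overlaps were compared with the overlap of independent lists, and covariances of fold changes with 50 simulated data sets without any effect.

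The tests were tested on simulated data, negative binomial counts with these libraries' depths and spread and known changes. edgeR found 71.2% to 83.3% of genes changed 4-fold and 43.3% to 52.2% of those changed 2-fold, but only 7.46% to 13.4% of those changed 1.5-fold, and 3% to 7.27% of its calls were false. DESeq2 found 84.8% to 87.9%, 55.2% to 68.7% and 19.4% to 25.4% of these, with 15.3% to 21.4% false calls. Other programs were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.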

Results

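Gene expression was measured in 12 libraries of poly-A RNA from RPE-1 cells, 3 in each of 4 groups. The groups were cells starved of serum and glucose, and starved cells given both for 4 h with solvent, with the Na+/H+ exchange inhibitor DMA or with the p300/CBP inhibitor C646. The starved libraries held 14910516 to 23950322 expected counts, the solvent libraries 23472623 to 28968510, the DMA libraries 20262061 to 22011436 and the C646 libraries 21929453 to 24784194. Transcripts encoded by mitochondrial DNA took 1.69% to 4.18% of the counts, and spike-in controls took 0.527% to 1.28%. Solvent library 1 stood apart from the other solvent libraries on a principal component that held 13.4% of the variance. The cell cycle gene CCNE2 measured 41.8 CPM in that library and 8.04 and 12.6 CPM in solvent libraries 2 and 3. Genes called uncertain share sequence with other genes or overlap them, and the strand setting of the counts is not stated.

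The comparison of solvent with starved cells asks what serum and glucose change within 4 h. Genes of the stress responses to missing amino acids and misfolded proteins fell, and heat shock genes and genes of ribosome assembly and G1 progression rose. These are list calls at a preset correlation, and none held with an estimated correlation (adjusted p = 0.10 to 0.52). HERPUD1 (chromosome 16, 56932048 to 56944863 on GRCh38), which acts in the disposal of proteins from the endoplasmic reticulum, fell by 4.36 ± 0.16 (log2, SE) from 568 ± 106 to 27.8 ± 1.61 CPM (mean ± SD, n = 3 per group, adjusted p = 4.2e-09). DDIT3, a stress-induced transcription factor, fell by 5.50 from 267 ± 42.0 to 5.91 ± 1.39 CPM (adjusted p = 1.5e-06), and is uncertain because 31.6% of its exons overlap an antisense gene. ID3, an inhibitor of helix-loop-helix factors, rose by 3.00 from 4.85 ± 0.659 to 38.6 ± 11.8 CPM (adjusted p = 8.4e-06).

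The test called 3704 of 15263 genes, 1921 higher and 1783 lower (51.9% higher). Scaling to the spike-in controls raised the median log2 change of all genes by 0.60 and called 3416 genes, 3227 higher and 189 lower (94.5% higher), so all changes here are relative to the other genes. Leaving out starved library 2 gave 2269 genes. The other largest rises were ANGPTL4 (4.25), a secreted regulator of lipoprotein lipase, ESM1 (3.27), IL7R (3.03), the interleukin-7 receptor, IFITM10 (2.85, uncertain) and FAM111B (2.75). Among the largest falls were also LURAP1L (-3.54), DDIT4 (-3.50, uncertain), an inhibitor of mTORC1 signalling, DNAJB9 (-3.43), a chaperone of the endoplasmic reticulum, and KLHL24 (-3.18). ESM1 missed the threshold without starved library 2 or solvent library 1 (adjusted p = 0.073 and 0.082). CCNE2 and FAM111B measured 1.30 and 1.74 without solvent library 1. IFITM10 missed the threshold without starved library 1, starved library 2 or solvent library 3 (0.069, 0.067 and 0.071). Of 87 named genes past the threshold, 56 stayed past it without any 1 of the 6 libraries. Leaving out starved library 1, 2 or 3 ended 20, 24 and 11 of the calls, and leaving out solvent library 1, 2 or 3 ended 20, 15 and 15 (highest adjusted p = 0.196). Those fits have no block. With the block and no solvent library 1, 9 of the 87 calls ended.

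In the panel of cell cycle genes, CCNE2, a cyclin of the G1 to S transition, rose by 2.32 ± 0.51 (adjusted p = 0.0061), and is uncertain because 37.1% of its exons overlap an antisense gene. CDC25A, a phosphatase that activates cyclin-dependent kinases, rose by 1.86 ± 0.32 (adjusted p = 0.0014). CCNE1 rose by 1.32 ± 0.36 (adjusted p = 0.016), and the kinase inhibitor CDKN1B fell by 0.70 ± 0.19 (adjusted p = 0.016). CCNE1 missed the threshold without starved library 1, starved library 2 or solvent library 1 (0.051, 0.069 and 0.095), and CDKN1B without starved library 3 or solvent library 1 (0.065 and 0.068). The changes of CCND1 (0.75 ± 0.28, adjusted p = 0.067) and MYC (-0.66 ± 0.26, adjusted p = 0.083) did not pass. Neither did those of E2F1 (0.11), CDKN1A (0.17) and EGR1 (0.04). FOS, an immediate early gene, fell by 1.85 ± 0.35 (adjusted p = 0.0023), TXNIP, a glucose-responsive gene, rose by 2.51 ± 0.61 (adjusted p = 0.011), and LDHA, lactate dehydrogenase, rose by 1.36 ± 0.18 (adjusted p = 2.0e-04). TXNIP had an adjusted p of 0.0501 without solvent library 3. CREBBP, which encodes CBP, fell by 0.84 ± 0.17 (adjusted p = 0.0036) and EP300, which encodes p300, fell by 0.49 ± 0.12 (adjusted p = 0.010). EP300 missed the threshold without starved library 2 (0.053) and measured 0.13 with spike-in scaling, where the calls of CREBBP (-0.21), CDKN1B (-0.10) and FOS (-1.20) also ended.

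Among lists of stress genes, 25 of 27 measured amino acid response and ATF4 targets fell and 1 rose (26 and 1 adjusted over the list alone, camera adjusted p = 6.9e-17, adjusted p = 0.11 with an estimated correlation, 5.2e-31 to 0.33 over its alternatives). CHAC1, which degrades glutathione, fell by 4.08. Of 19 chaperones and genes of the unfolded protein response (UPR), 15 fell (16 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.4e-11, adjusted p = 0.19 with an estimated correlation, 4.4e-17 to 0.34 over its alternatives). Of 24 genes of sterol synthesis and uptake, 17 fell (18 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.6e-08, adjusted p = 0.10 with an estimated correlation, 2.4e-09 to 0.26 over its alternatives). They included INSIG1 (-1.57), a sensor of sterols, and STARD4 (-1.96). With spike-in scaling the list's median of -0.73 became -0.07. Of 22 quiescence and FOXO targets, 11 fell and 2 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.0038, adjusted p = 0.35 with an estimated correlation, 5.7e-04 to 0.36 over its alternatives). CCNG2, an atypical cyclin of resting cells, fell by 1.99, YPEL2 fell by 2.16 and SESN1 rose by 0.87, and the list's median of -0.62 became -0.03 with spike-in scaling. SESN1 missed the threshold without starved library 2 or solvent library 3 (0.060 and 0.054).

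All 13 called members of the 16 heat shock genes rose (13 adjusted over the list alone, camera adjusted p = 6.5e-10, adjusted p = 0.10 with an estimated correlation, 5.6e-12 to 0.26 over its alternatives). They included the co-chaperones DNAJA1 (1.80) and CHORDC1 (1.62). Of 30 ribosome biogenesis genes, 20 rose and 2 fell (22 and 2 adjusted over the list alone, camera adjusted p = 8.2e-08, adjusted p = 0.10 with an estimated correlation, 5.8e-08 to 0.26 over its alternatives). LYAR and NOP16, nucleolar proteins, rose by 1.22 and 1.21. Of 14 G1 regulators, 8 rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.0038, adjusted p = 0.52 with an estimated correlation, 2.7e-05 to 0.52 over its alternatives). Of 22 glycolysis genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.52 with an estimated correlation, 0.0047 to 0.54 over its alternatives). The enzyme PGK1 rose by 0.64 while the glucose transporter SLC2A1 fell by 1.24. With spike-in scaling PGK1 measured 1.21 and the call of SLC2A1 ended (-0.65, adjusted p = 0.14). The glycolysis call ended with spike-in scaling (0.10), without starved library 1 (0.11) and without solvent library 2 (0.053). Of 30 DNA replication and E2F targets, 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.79 with an estimated correlation, 6.4e-05 to 0.97 over its alternatives). MCM10, an initiator of replication, rose by 1.57 and the licensing factor CDT1 fell by 1.27. MCM10 held 40.4 CPM in solvent library 1 and 9.46 and 13.4 CPM in solvent libraries 2 and 3. With spike-in scaling the call of CDT1 ended (-0.79, adjusted p = 0.14) and MCM10 measured 1.87. That list's call ended without starved library 1 (0.16) and without solvent library 1 (0.70, and 0.97 with the block), and MCM10 missed the threshold without starved library 1, starved library 3 or solvent library 1 (0.077, 0.067 and 0.095).

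Of 30 histone acetylation enzymes and readers, 14 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0040, adjusted p = 0.52 with an estimated correlation, 0.0021 to 0.52 over its alternatives). KAT6B, an acetyltransferase, fell by 1.20, and HDAC1, a deacetylase, rose by 0.57. With spike-in scaling the list's median of -0.41 became 0.22 and its call ended (0.15). Of 28 lysosome and TFEB targets, 9 fell (9 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0038, adjusted p = 0.53 with an estimated correlation, 1.6e-04 to 0.53 over its alternatives), and the median of -0.31 became 0.29 with spike-in scaling. GABARAPL1, an autophagy gene, fell by 1.40. Of 30 nuclear genes of oxidative phosphorylation, 2 rose (camera adjusted p = 0.039, adjusted p = 0.79 with an estimated correlation, 9.6e-05 to 0.79 over its alternatives). Adjusted over the list alone edgeR called 0 of the 30, with 5 at an unadjusted p under 0.05 and 2 past the threshold by DESeq2. That list's call ended with the stricter filter (0.051) and without starved library 1, starved library 2, solvent library 2 or solvent library 3 (0.35, 0.10, 0.13 and 0.062). The other 18 lists did not pass (adjusted p = 0.14 to 0.92), and 4 of them did so in at least 1 alternative. They include acid and bicarbonate transport, with 2 of 22 genes higher and 3 lower (2 and 4 adjusted over the list alone). Another is the immediate early genes, with 4 of 23 higher and 3 lower (6 and 3 adjusted over the list alone). No list's call held with an estimated correlation.

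**Figure D1:**
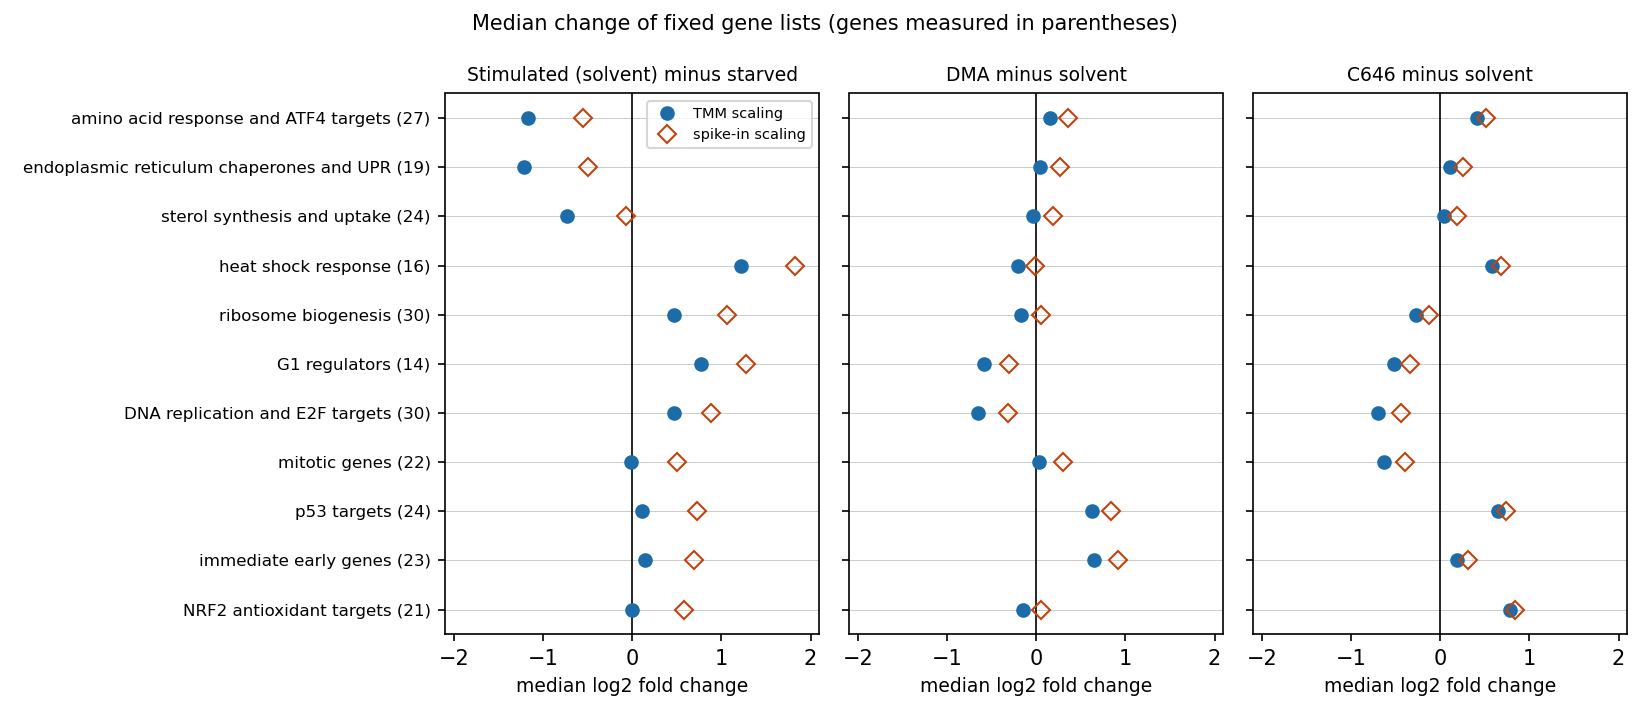
Median log2 fold change of 11 gene lists in solvent against starved cells and in each inhibitor against solvent, with TMM scaling (filled) and spike-in scaling (open), and the number of genes measured in parentheses. Spike-in scaling moves the medians up, and changes the sign of mitotic genes and NRF2 targets after stimulation and of ribosome biogenesis, NRF2 targets and sterol synthesis with DMA.

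The comparison of DMA with solvent asks what an inhibitor of Na+/H+ exchange changes during stimulation. With DMA, lists of p53 targets and immediate early genes were higher and DNA replication genes were lower at a preset correlation. None of these calls held with an estimated correlation in the fit without a block (adjusted p = 0.37, 0.062 and 0.72), and 5 of 24, 3 of 23 and 1 of 30 members passed. DUSP5 (chromosome 10, 110497838 to 110511544 on GRCh38), a phosphatase that inactivates ERK, rose by 1.81 ± 0.14 (log2, SE) from 109 ± 8.93 to 383 ± 36.8 CPM (n = 3 per group, adjusted p = 6.6e-05). CDKN1A, the kinase inhibitor p21, rose by 1.28 from 409 ± 104 to 992 ± 85.1 CPM (adjusted p = 0.018), and missed the threshold without solvent library 1 or 2 or DMA library 2 (0.089, 0.058 and 0.076). FAM111B, a protease of replicating cells, fell by 3.04 from 32.9 ± 28.7 to 3.99 ± 1.15 CPM (adjusted p = 0.018), and by 2.04 without solvent library 1, which held 65.8 CPM against 13.5 and 19.3 in solvent libraries 2 and 3. It missed the threshold without DMA library 2 or 3 (0.10 and 0.0504).

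The test called 267 genes, 112 higher and 155 lower (41.9% higher), and 1560 with the replicate number as a block. Spike-in scaling raised the median of all genes by 0.22 and called 91, 85 higher and 6 lower (93.4% higher), so changes are relative to the other genes. Leaving out solvent library 1 or 2 gave 8 and 30 genes, and leaving out DMA library 2 or 3 gave 1 and 119. The other largest rises were the RNA polymerase III transcript RN7SK (2.76, uncertain), ZBTB20 (1.92, uncertain), TOX (1.48), the signalling inhibitor SPRY4 (1.47) and PRAG1 (1.43). All of the sequence of RN7SK occurs in other annotated genes, and its whole exon overlaps another gene on the same strand. RN7SK measured 107, 90.8 and 12.2 CPM in DMA libraries 1, 2 and 3 and at most 11.7 with solvent, and ZBTB20 24.3, 24.3 and 6.70 against at most 5.57, so both rises rest on DMA libraries 1 and 2. The other largest falls were CCNE2 (-2.81, uncertain), ADAMTS15 (-2.20), WDR76 (-1.86), the checkpoint mediator CLSPN (-1.79) and AP3M2 (-1.58). Without solvent library 1, CCNE2, WDR76 and CLSPN measured -1.80, -0.98 and -1.0, and of the 5 only AP3M2 stayed past the threshold. In the panel, E2F1, an activator of S phase genes, fell by 1.26 ± 0.27 (adjusted p = 0.037), EP300 rose by 0.63 ± 0.12 (adjusted p = 0.023), and CCNE1 (-1.28 ± 0.35, adjusted p = 0.080) and CCND1 (-0.58 ± 0.28, adjusted p = 0.27) did not pass. E2F1 held 27.3 CPM in solvent library 1 and 12.5 and 12.6 CPM in solvent libraries 2 and 3. With spike-in scaling the calls of E2F1 (-0.88, adjusted p = 0.48) and EP300 (0.81, adjusted p = 0.43) ended. With the block, CCNE1 and CCND1 passed (adjusted p = 0.029 and 0.029). Of 23 named genes past the threshold, DUSP5 alone stayed past it without any 1 of the 6 libraries. Leaving out solvent library 1, 2 or 3 ended 20, 14 and 2 calls and leaving out DMA library 1, 2 or 3 ended 11, 22 and 11 (highest adjusted p = 0.181). Those fits have no block and so ignore the pairing by number. With the block and no solvent library 1, 5 of the 23 calls ended.

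Of 24 p53 targets, 5 rose with DMA (14 adjusted over the list alone, 13 over all genes with the block, camera adjusted p = 9.1e-11, adjusted p = 0.37 with an estimated correlation, 1.5e-14 to 0.70 over its alternatives). BTG2, an antiproliferative gene, rose by 1.19. Of 23 immediate early genes, 3 rose (14 adjusted over the list alone, 14 over all genes with the block, camera adjusted p = 4.2e-10, adjusted p = 0.062 with an estimated correlation, 1.5e-13 to 0.062 over its alternatives). Of 30 DNA replication and E2F targets, 1 fell (17 adjusted over the list alone, 5 over all genes with the block, camera adjusted p = 3.4e-10, adjusted p = 0.72 with an estimated correlation, 5.0e-17 to 0.72 over its alternatives). Solvent library 1 held the highest level of these genes, and the median log2 ratio of the list, DMA over solvent library of the same number, was -1.07, -0.19 and -0.45 for numbers 1, 2 and 3. The list's call held without that library, also with the block (adjusted p = 1.3e-05 and 2.0e-04). Of 14 G1 regulators, 3 fell (5 lower and 1 higher adjusted over the list alone, 6 and 1 over all genes with the block, camera adjusted p = 0.015, adjusted p = 0.73 with an estimated correlation, 1.9e-06 to 0.73 over its alternatives). E2F2 fell by 2.55, with 10.2, 1.83 and 3.53 CPM in solvent libraries 1, 2 and 3. Its call ended with spike-in scaling (-2.05, adjusted p = 0.054). The call of the G1 list ended without solvent library 1 (0.099) and without DMA library 3 (0.052). Of 13 mitochondrially encoded genes, 2 fell (7 adjusted over the list alone, 5 over all genes with the block, camera adjusted p = 1.5e-05, adjusted p = 0.72 with an estimated correlation, 2.0e-06 to 0.72 over its alternatives). MT-CYB, cytochrome b, fell by 0.87 and MT-ND3, a subunit of complex I, fell by 0.67. Of 30 ribosome biogenesis genes, 2 fell, also adjusted over the list alone (camera adjusted p = 0.0050, adjusted p = 0.66 with an estimated correlation, 8.6e-04 to 0.70 over its alternatives). GNL3 fell by 0.79 and NOP56 fell by 0.57, and the list's median of -0.18 became 0.05 with spike-in scaling, where its call ended (0.24), as it did without DMA library 2 (0.071). Over all lists 19 members passed, 1 without solvent library 1 or DMA library 2, 5 without solvent library 2 and 12 without DMA library 3. No call of these 6 lists held with an estimated correlation in the fit without a block, and the other 24 lists did not pass (adjusted p = 0.10 to 0.91), 7 of which passed in at least 1 alternative. The list of immediate early genes passed with the block and an estimated correlation (0.012).

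The comparison of C646 with solvent asks what an inhibitor of p300 and CBP changes during stimulation. With C646, lists of antioxidant, heat shock and p53 target genes were higher, and DNA replication and mitotic genes were lower at a preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.082, 0.087, 0.12, 0.26 and 0.33). HSPA4L (chromosome 4, 127781821 to 127840733 on GRCh38), a chaperone of the HSP110 family, rose by 1.71 ± 0.18 (log2, SE) from 68.4 ± 3.60 to 224 ± 43.6 CPM (n = 3 per group, adjusted p = 0.0012). HMOX1, heme oxygenase, rose by 3.81 from 33.4 ± 9.88 to 468 ± 310.0 CPM (adjusted p = 0.0076), by 3.12 without C646 library 3, and missed the threshold without solvent library 1 (0.063). CDKN1A rose by 1.56 from 409 ± 104 to 1208 ± 254 CPM (adjusted p = 0.0074).

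The test called 185 genes, 124 higher and 61 lower (67.0% higher), and 1199 with the replicate number as a block. Spike-in scaling raised the median of all genes by 0.13 and called 100, 84 higher and 16 lower (84.0% higher), so changes are relative to the other genes. Leaving out solvent library 1 or 2 gave 24 and 96 genes, and leaving out C646 library 1, 2 or 3 gave 35, 114 and 66. The other largest rises were the amino acid transporter SLC43A2 (3.08), PCLO (3.03), the transcription factor TBX2 (2.65), RNF150 (2.50) and the heat shock protein HSPA1A (2.31, uncertain). The largest falls were CCNE2 (-2.47, uncertain), FAM111B (-2.44), ZNF367 (-2.09), WDR76 (-1.92), the chemokine CCL2 (-1.83) and CDCA7 (-1.70). Without solvent library 1, CCNE2, FAM111B, ZNF367, WDR76 and CDCA7 measured -1.45, -1.44, -1.31, -1.05 and -1.07, and of the 6 only ZNF367 and WDR76 stayed past the threshold. In the panel, E2F1 (-1.01 ± 0.27, adjusted p = 0.078), EP300 (0.41 ± 0.12, adjusted p = 0.10) and CREBBP (0.60 ± 0.17, adjusted p = 0.097) did not pass. With the block, E2F1, EP300 and CREBBP passed (adjusted p = 0.0486, 0.031 and 0.012). Of 30 named genes past the threshold, 7 stayed past it without any 1 of the 6 libraries, among them CDKN1A, CCNG2, HSPA4L and SLC43A2. Leaving out solvent library 1, 2 or 3 ended 20, 8 and 9 calls and leaving out C646 library 1, 2 or 3 ended 21, 15 and 16 (highest adjusted p = 0.221). Those fits have no block and so ignore the pairing by number. With the block and no solvent library 1, 5 of the 30 calls ended.

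Of 21 NRF2 antioxidant targets, 7 rose with C646 (19 adjusted over the list alone, 16 over all genes with the block, camera adjusted p = 8.2e-18, adjusted p = 0.082 with an estimated correlation, 3.8e-28 to 0.11 over its alternatives). SLC7A11, the cystine transporter, rose by 1.83. Of 16 heat shock genes, 2 rose (9 adjusted over the list alone, 9 over all genes with the block, camera adjusted p = 9.0e-11, adjusted p = 0.087 with an estimated correlation, 1.6e-14 to 0.17 over its alternatives). Of 24 p53 targets, 5 rose (14 adjusted over the list alone, 12 over all genes with the block, camera adjusted p = 1.8e-13, adjusted p = 0.12 with an estimated correlation, 2.8e-17 to 0.22 over its alternatives). MDM2, the ubiquitin ligase of p53, rose by 1.22. Of 30 DNA replication and E2F targets, edgeR called 0 over all genes, with 25 at an unadjusted p under 0.05 and 14 past the threshold by DESeq2, all 14 lower. Adjusted over the list alone, 25 fell, and 9 fell over all genes with the block (camera adjusted p = 2.2e-15, adjusted p = 0.26 with an estimated correlation, 1.6e-22 to 0.33 over its alternatives). The median log2 ratio of that list, C646 over solvent library of the same number, was -1.42, -0.25 and -0.46 for numbers 1, 2 and 3. Of 22 mitotic genes, 1 fell (13 adjusted over the list alone, 5 over all genes with the block, camera adjusted p = 8.2e-11, adjusted p = 0.33 with an estimated correlation, 8.7e-14 to 0.34 over its alternatives). It was BUB1B, a spindle checkpoint kinase, which fell by 0.92. Of 30 ribosome biogenesis genes, 3 fell (9 adjusted over the list alone, 8 over all genes with the block, camera adjusted p = 1.8e-08, adjusted p = 0.082 with an estimated correlation, 1.4e-09 to 0.17 over its alternatives). NOLC1 fell by 0.65.

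Of 28 lysosome and TFEB targets, 2 rose (5 adjusted over the list alone, 7 over all genes with the block, camera adjusted p = 1.5e-06, adjusted p = 0.29 with an estimated correlation, 1.6e-08 to 0.29 over its alternatives). They were GLA (1.12), alpha-galactosidase, and CTSL (0.60), cathepsin L. Of 22 quiescence and FOXO targets, 3 rose (4 adjusted over the list alone, 6 over all genes with the block, camera adjusted p = 9.0e-05, adjusted p = 0.18 with an estimated correlation, 2.6e-06 to 0.20 over its alternatives). CCNG2 rose by 1.87 and YPEL2 by 1.53. Of 17 NF-kappaB and inflammatory genes, 2 fell, CCL2 and BIRC3 (-1.51), an inhibitor of apoptosis (camera adjusted p = 0.0018, adjusted p = 0.18 with an estimated correlation, 2.2e-07 to 0.25 over its alternatives). Adjusted over the list alone, 4 fell and 1 rose, and 5 fell and 1 rose over all genes with the block. Of 27 amino acid response and ATF4 targets, 1 rose (4 adjusted over the list alone, 4 over all genes with the block, camera adjusted p = 2.2e-04, adjusted p = 0.41 with an estimated correlation, 2.3e-06 to 0.50 over its alternatives). Of 14 G1 regulators, 1 fell (6 lower and 1 higher adjusted over the list alone, 3 and 1 over all genes with the block, camera adjusted p = 0.0028, adjusted p = 0.40 with an estimated correlation, 2.1e-06 to 0.40 over its alternatives). Of 13 mitochondrially encoded genes, 1 fell (5 adjusted over the list alone, 4 over all genes with the block, camera adjusted p = 7.9e-05, adjusted p = 0.40 with an estimated correlation, 1.2e-05 to 0.45 over its alternatives). Of 30 histone acetylation enzymes and readers, 1 rose (3 adjusted over the list alone, 4 over all genes with the block, camera adjusted p = 0.0071, adjusted p = 0.40 with an estimated correlation, 3.2e-04 to 0.40 over its alternatives). It was the coactivator NCOA3 (0.53), and the list's call ended without C646 library 2 (0.078).

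The 18 cytoskeletal SRF and MRTF targets were higher as a set with C646 (camera adjusted p = 0.035, adjusted p = 0.56 with an estimated correlation, 8.4e-04 to 0.57 over its alternatives). For single members edgeR called 0, over all genes and adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2. That call ended without solvent library 3, C646 library 1 or C646 library 2 (0.11, 0.23 and 0.14), and with the block and no solvent library 1 (0.12). Over all lists 31 members passed, 5 without solvent library 1, and 6, 18 and 14 without C646 library 1, 2 or 3. None of these 14 lists passed with an estimated correlation. The other 16 did not pass (adjusted p = 0.0501 to 0.86), and 7 of them did so in at least 1 alternative. With the block, the MondoA glucose response and TGF-beta targets passed (0.026 and 0.049, 0.0011 to 0.40 and 0.0020 to 0.49 over their alternatives). Those are calls at the preset correlation, and neither list passed with an estimated correlation in the fit without a block.

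**Figure D2:**
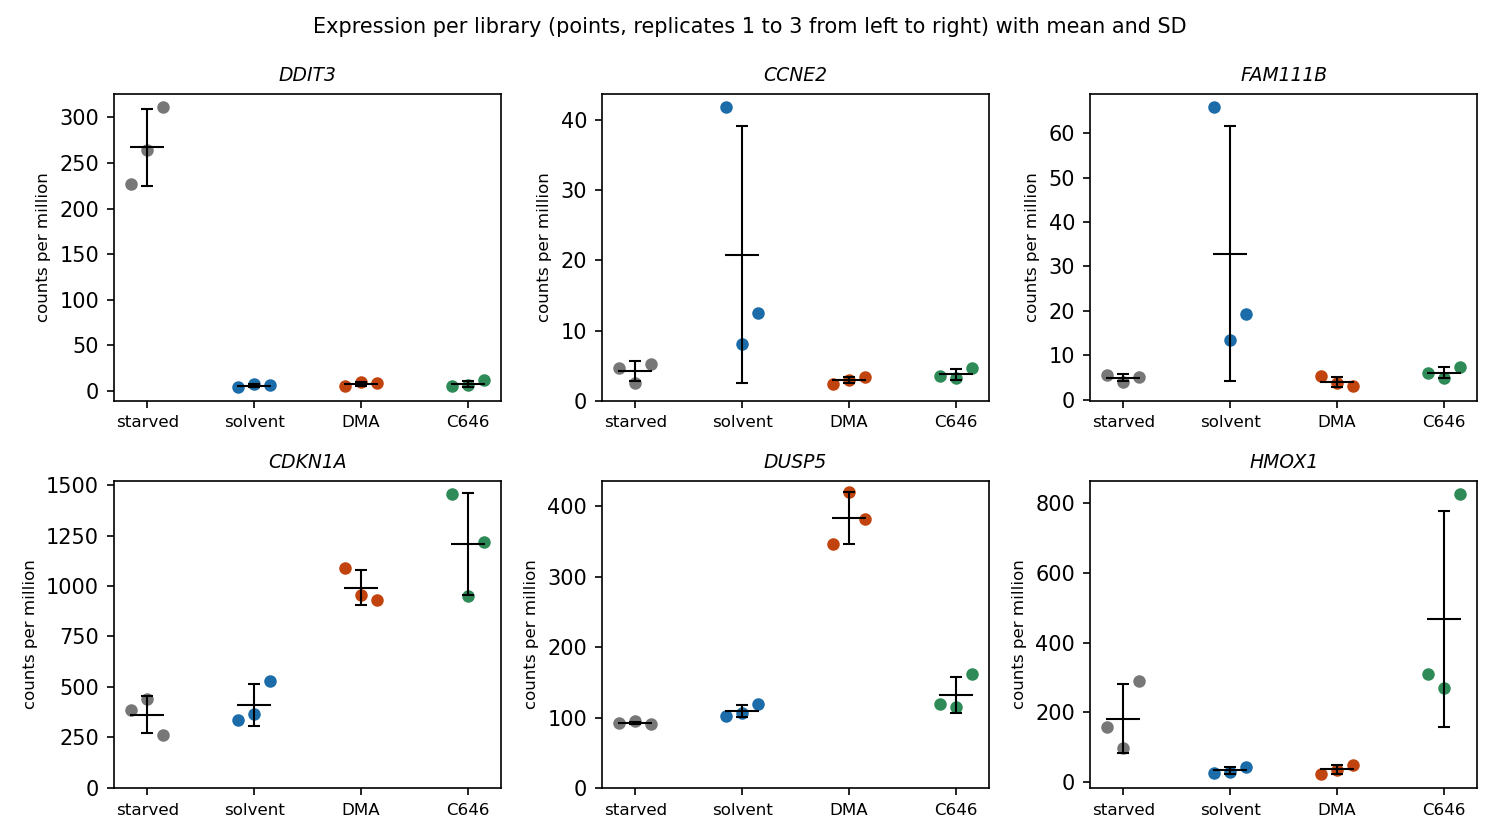
CPM of 6 genes in each library (points, replicates 1 to 3 from left to right) with group means (lines) and SD (bars). DDIT3 was lower in every stimulated group, CCNE2 and FAM111B were highest in solvent library 1, CDKN1A was higher with both inhibitors, DUSP5 with DMA and HMOX1 with C646.

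Both inhibitors together changed 23 genes in one direction, 11 higher and 12 lower, and 1 gene, HKDC1, in opposite directions (23 with the block, of which 12 higher with DMA and 11 higher with C646, where independent lists would share 27.1 and 34.4). The fall of HKDC1 with DMA missed the threshold without solvent library 1, 2 or 3 (0.10, 0.071 and 0.068) and without DMA library 1 or 2 (0.071 and 0.15). The 12 lower genes include FAM111B, CCNE2 (uncertain), WDR76 and, chosen after their values were seen, RPA2 (-0.61 with DMA and -0.71 with C646), a subunit of the replication protein A complex, and SMC6 (-0.87 and -0.84). The 11 higher genes include CDKN1A, BTG2, PRAG1 and, also chosen after their values were seen, the transcription factor KLF5 (1.01 and 0.98). Independent lists would share 1.53 genes in one direction. Both comparisons use the same 3 solvent libraries, which cannot be split into parts of at least 2. The covariance of the fold changes was 0.129 against 0.0625 in the simulated data (0.0552 to 0.0724), and their Pearson correlation was 0.484 against 0.494. Simulated libraries vary independently, so a solvent library that stands apart or a pairing by number is not reproduced. Part or all of the excess may therefore come from the shared controls. With the block 311 genes changed in one direction, 139 higher and 172 lower, where independent lists would share 29.9 and 31.2. Leaving out solvent library 1 or DMA library 2 gave 0 by edgeR, with 425 and 624 genes at an unadjusted p under 0.05 in both. With the block and no solvent library 1, 16 were higher and 21 lower, where independent lists would share 2.73 and 1.92. In that fit 4 genes were higher with DMA and lower with C646 and 3 the reverse (1.48 and 3.54 for independent lists). Solvent libraries 2 and 3 still enter both comparisons there. Leaving out solvent library 2 gave 7, C646 library 1, 2 or 3 gave 3, 9 and 12, and DMA library 3 gave 10. DESeq2 gave 196 with all libraries.

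Of the 1921 genes induced by stimulation, 54 were lower with DMA and 35 with C646, and 6 with both. Independent lists would share 19.5 and 7.68. The solvent libraries enter both sides of this comparison with opposite signs, and the covariance of stimulation with DMA was -0.0824 against -0.0628 simulated, and with C646 -0.0797 against -0.0635. Fewer induced genes were higher with DMA, 21, or with C646, 24, where independent lists would share 14.1 and 15.6. With the block, 330 induced genes were lower with DMA and 286 with C646, where independent lists would share 150.5 and 103. Leaving out starved library 1 or 2 gave 30 and 27 for DMA and 14 and 17 for C646, and leaving out solvent library 1 gave 3 and 2. With the block and no solvent library 1 they were 98 and 57, where independent lists would share 39.9 and 16.9. Induced genes higher with an inhibitor were not counted in that fit. Solvent library 2 left out gave 13 for DMA, and solvent library 3 left out gave 20 for C646. Leaving out DMA library 2 gave 0 by edgeR (394 at an unadjusted p under 0.05), DMA library 3 gave 22, and C646 library 1, 2 or 3 gave 1, 7 and 7. For C646, leaving out DMA library 2, which enters the common fit, gave 19. DESeq2 gave 187 and 189 with all libraries, and spike-in scaling 4 and 11.

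The comparison of DMA with C646 tests the difference between the inhibitors. Antioxidant and heat shock genes were lower with DMA than with C646, and mitotic, immediate early and inflammatory genes were higher as lists. The last 3 calls ended with an estimated correlation (adjusted p = 0.46, 0.073 and 0.073), as did that of heat shock genes when the block was added (0.11), and 2 of 22 mitotic genes passed. HKDC1 (chromosome 10, 69220303 to 69267559 on GRCh38), a hexokinase-like protein, was lower by 3.47 ± 0.30 (log2, SE), with 2.82 ± 1.10 CPM under DMA and 31.3 ± 5.59 under C646 (n = 3 per group, log2 -3.47, adjusted p = 1.5e-04). HMOX1 differed by -3.69 ± 0.51 (adjusted p = 0.0045) and GCLC, an enzyme of glutathione synthesis, by -2.47 ± 0.37 (adjusted p = 0.0053). DUSP5 differed by 1.54 ± 0.14 (adjusted p = 1.5e-04) and the mitotic kinase AURKA by 1.04 ± 0.17 (adjusted p = 0.0076).

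The test called 441 genes, 144 higher and 297 lower with DMA (32.7% higher), and 1498 with the block. Spike-in scaling moved the median of all genes by 0.098 and called 120, 53 higher and 67 lower (44.2% higher). With that scaling the SE of some genes grew, as that of HKDC1 from 0.30 to 0.41, so an ended call need not mean a smaller change. The adjusted p of HKDC1 still fell from 1.5e-04 to 8.2e-12, at a smaller change (-3.30). Counts of calls under TMM and spike-in scaling are therefore not directly comparable. Leaving out C646 library 1, 2 or 3 gave 185, 218 and 240 genes, and leaving out DMA library 2 or 3 gave 192 and 180. The other largest differences were PLXNA2 (2.78), the chemokine CXCL8 (2.54), MTSS1 (2.47), the cytokine IL1B (2.04), PCLO (-2.88) and SLC43A2 (-2.71). In the panel no gene passed, with CDKN1A at -0.28 ± 0.21 (adjusted p = 0.56), which does not show that the inhibitors act alike on it. EGR1 and TXNIP passed with the block (adjusted p = 0.011 and 0.0019). Of 29 named genes past the threshold, 13 stayed past it without any 1 of the 6 libraries, among them HKDC1, HMOX1, DUSP5, SPRY4 and AURKA. Leaving out C646 library 1, 2 or 3 ended 14, 11 and 9 calls, and leaving out DMA library 1, 2 or 3 ended 9, 9 and 12 (highest adjusted p = 0.160).

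Of 21 NRF2 antioxidant targets, 12 were lower with DMA than with C646 (19 adjusted over the list alone, 19 over all genes with the block, camera adjusted p = 4.6e-21, adjusted p = 0.0469 with an estimated correlation, 1.1e-34 to 0.0469 over its alternatives). Of 16 heat shock genes, 10 were lower (13 adjusted over the list alone, camera adjusted p = 5.3e-15, adjusted p = 0.0469 with an estimated correlation, 4.8e-19 to 0.11 over its alternatives). The calls of these lists held with an estimated correlation, but that of the heat shock genes ended with the block and an estimated correlation (0.11). Of 22 mitotic genes, 2 were higher (16 adjusted over the list alone, 5 over all genes with the block, camera adjusted p = 2.6e-11, adjusted p = 0.46 with an estimated correlation, 1.1e-13 to 0.52 over its alternatives). CCNB2, a mitotic cyclin, differed by 0.73. Of 23 immediate early genes, 5 were higher (10 higher and 1 lower adjusted over the list alone and, with the block, over all genes, camera adjusted p = 4.8e-06, adjusted p = 0.073 with an estimated correlation, 1.3e-07 to 0.073 over its alternatives). Of 17 NF-kappaB and inflammatory genes, 4 were higher (6 higher and 1 lower adjusted over the list alone, 7 and 1 over all genes with the block, camera adjusted p = 1.4e-05, adjusted p = 0.073 with an estimated correlation, 6.6e-10 to 0.19 over its alternatives). CSF2, a growth factor of myeloid cells, differed by 2.96. Of 28 lysosome and TFEB targets, 4 were lower (5 adjusted over the list alone, camera adjusted p = 0.0010, adjusted p = 0.57 with an estimated correlation, 6.2e-05 to 0.57 over its alternatives), with GLA at -1.34, and this call ended without DMA library 1 (0.078). Of 18 SRF and MRTF targets, 1 was lower, MYL9 (-0.68), a myosin light chain (2 adjusted over the list alone, 3 over all genes with the block, camera adjusted p = 0.0016, adjusted p = 0.57 with an estimated correlation, 5.6e-06 to 0.57 over its alternatives). Of 30 ribosome biogenesis genes, 2 were higher (4 higher and 1 lower adjusted over the list alone, the same over all genes with the block, camera adjusted p = 0.0461, adjusted p = 0.57 with an estimated correlation, 0.0039 to 0.60 over its alternatives), and the list's call ended with the block (0.073), the stricter filter (0.055) and spike-in scaling (0.17). It also ended without DMA library 1 or 3 (0.29 and 0.076) and without C646 library 1 or 3 (0.075 and 0.11). Over all lists 46 members passed, 30 and 24 without DMA library 2 or 3 and 22 and 28 without C646 library 1 or 2. The other 22 lists did not pass (adjusted p = 0.085 to 0.98), and 6 of them did so in at least 1 alternative.

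The inhibitor groups were also compared with starved cells. DMA differed from starved in 4109 genes, 2126 higher and 1983 lower (51.7% higher), and C646 in 3750, 1968 higher and 1782 lower (52.5% higher). Spike-in scaling gave 6574 genes, 97.9% higher, with a median shift of 0.81 for DMA, and 5220 genes, 97.6% higher, with a shift of 0.73 for C646. A shift in a library's scale enters every gene, so these counts do not measure separate changes. For human reads per spike-in read itself, each group against starved gave an exact permutation p of 0.1. Of the 3704 genes called after stimulation, 2473 passed in the same direction with DMA and 2370 with C646, and 5 passed in the opposite direction with each. The same 3 starved libraries enter all of these comparisons and no value without a response was computed, so these counts do not measure how much of the response remained. HERPUD1 stood at -4.43 ± 0.16 (adjusted p = 3.6e-09) with DMA and -4.21 ± 0.16 (adjusted p = 6.1e-09) with C646, and ID3 at 3.91 ± 0.24 (adjusted p = 1.5e-06) and 3.31 ± 0.24 (adjusted p = 3.2e-06). FAM111B stood at -0.30 ± 0.50 (adjusted p = 0.70) and 0.30 ± 0.49 (adjusted p = 0.70). Of the 12 genes with the largest changes after stimulation, 11 passed in the same direction with DMA, all except FAM111B, and 10 with C646, all except FAM111B and ESM1, at 1.35 ± 0.87 (adjusted p = 0.29).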

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

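The tests of solvent library 1, of inhibitor treatment, of DMA in every library and of the amount of spike-in added, and all spike-in values, were chosen after the results were seen.

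HKDC1, a hexokinase-like gene, moved in opposite directions under the inhibitors, the only such gene by edgeR with all libraries and no block. With the block, 12 genes were higher with DMA and lower with C646 and 11 the reverse, where independent lists would share 27.1 and 34.4. Against solvent HKDC1 fell by 1.38 ± 0.29 with DMA (log2, SE, adjusted p = 0.035, below all 3 solvent libraries in 3 of 3 libraries) and rose by 2.09 ± 0.28 with C646 (adjusted p = 0.0069, above them in 3 of 3). The call with DMA ended in 8 of 14 alternatives (highest adjusted p = 0.25, with spike-in scaling), among them without solvent library 1, 2 or 3 (0.10, 0.071 and 0.068) and without DMA library 1 or 2 (0.071 and 0.15). The call with C646 held in 14 of 14 (highest adjusted p = 0.0473). The direct test of the difference gave -3.47 ± 0.30 (adjusted p = 1.5e-04) and held in 14 of 14 alternatives (highest adjusted p = 0.0051), those without 1 of the 6 DMA and C646 libraries included. No technical or biological explanation was tested for this gene.

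More human reads per spike-in read were counted after stimulation. Spike-ins served gene comparisons only as an alternative scaling, and their amount is not stated. Starved libraries held 97.9 ± 18.9 human reads per spike-in read (SD, n = 3) and solvent libraries 144 ± 47.8, a ratio of 1.47, higher in 3 of 3 numbers (exact permutation p = 0.3). DMA libraries held 167 ± 28.8 (ratio 1.70, exact permutation p = 0.1) and C646 libraries 158 ± 33.4 (ratio 1.61, exact permutation p = 0.1), each higher in 3 of 3 numbers, and 0.1 is the smallest p that 3 against 3 libraries can give. Within numbers 1, 2 and 3 the ratio to starved was 1.21, 1.83 and 1.32 for solvent, 1.74, 1.75 and 1.64 for DMA and 1.55, 1.76 and 1.51 for C646, and the libraries of one group differed by up to 1.48-fold in starved, 1.39-fold in DMA and 1.52-fold in C646. If a few spike-in sequences set the ratio, under 60% of them would be lower per human read, but 100% (21 of 21) were, which argues against that source. A change in the amount of spike-in added per library stays open, since solvent libraries differ by up to 2.02-fold and an amount that differs between groups cannot be excluded, and so does a biological rise in RNA per sample, which may be the source but cannot be told apart from it.

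DNA replication and E2F targets were lower with both inhibitors as a set, a call that ended with an estimated correlation (adjusted p = 0.72 with DMA and 0.26 with C646, 5.0e-17 to 0.72 and 1.6e-22 to 0.33 over the alternatives). After removal of the trend with GC content and transcript length the list's median was -0.55 with DMA (95% bootstrap range -0.71 to -0.47) and -0.75 with C646 (-0.85 to -0.56). That is at least 86.2% of the uncorrected -0.64 and -0.69, while the correction moved other genes (SD 0.13), so these trends are unlikely to be the whole source. The bootstrap resampled the list's genes, not the libraries, so its ranges leave out the spread between libraries. With spike-in scaling the medians of the fit without a block went from -0.66 and -0.70 to -0.32 and -0.45. Without solvent library 1, which held the highest levels, the call held at the preset correlation (adjusted p = 1.3e-05 with DMA and 4.6e-11 with C646, and 2.0e-04 and 5.4e-10 with the block). The medians were then -0.29 and -0.40, with 27 and 30 of 30 members below 0. Libraries of one group differed by up to 0.37 when solvent library 1 is left out (solvent libraries 2 and 3 over solvent library 1 gave -1.03 and -0.74). That 0.37 is starved library 2 over starved library 1, a group outside both comparisons. In the stimulated groups the largest was 0.24, solvent library 3 over 2. The -0.29 lies inside 0.37 but beyond 0.24. The ratio nearest 0 of the 4 within numbers 2 and 3, at -0.19, lies inside both. An estimated correlation was not run without solvent library 1, which therefore stays open as part or the whole of the source. Inhibitor treatment also stays open, because the ratios were below 0 in 6 of 6 pairs but beyond 0.37 in only 4 of 6. With C646 in number 2 the ratio was -0.25, inside 0.37 but beyond 0.24.

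The RNA polymerase III transcripts RN7SK, RN7SL1, RN7SL2, RMRP and RPPH1, all uncertain because nearly all of their sequence occurs in other genes, had a median log2 ratio over the solvent library of the same number of 3.65, 3.49 and -0.10 in DMA libraries 1, 2 and 3. Carry-over of RNA without a poly-A tail is a candidate explanation and would also raise other such RNAs, for which histone, small nuclear and Cajal body RNAs were listed. The median of 18 such genes was 0.42 (95% bootstrap range 0.11 to 0.82), on both sides of the 0.5 set as the limit, with 0.70 in number 1 and -0.03 in number 2. This bootstrap also resampled genes, not libraries. Of the 18, 17 are histones that passed the filter in poly-A libraries, and whether their transcripts lack a tail here was not tested. The other, SNORD3A, was listed with the small nuclear RNAs but is a small nucleolar RNA. It stood 5.40, 1.08 and 1.42 higher in numbers 1, 2 and 3 and so does not follow the polymerase III transcripts in number 3. Carry-over cannot be told apart from other sources. DMA treatment in every library would need a ratio of at least 1 in each, and the lowest was -0.10, but with 1 of 3 libraries apart this stays open too.

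The splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real split was 1 of 10 with as many genes in all 9 results, and the highest other split gave 0 genes past the threshold by edgeR in each (DESeq2 was not run on splits). Every other split puts libraries of both groups on each side. A real difference then adds to the spread within the sides, so the 0 cannot serve as support. The real values were 3704 genes for stimulation, 267 for DMA, 185 for C646, 441 for DMA against C646, 4109 and 3750 for DMA and C646 against starved, 23 for both inhibitors in one direction, and 54 and 35 for induced genes lower with DMA and C646. At an unadjusted p under 0.05 the real splits gave 5542, 2960, 2567, 2651, 5956, 5621, 874, 543 and 543 genes in that order, and the highest others 1220, 1930, 1699, 2220, 1283, 1320, 439, 343 and 238. Besides the real split, 3 splits part all 3 pairs of equal number and the others part 1. Where the numbers pair the libraries, the 3 gave at most 264, 763, 261, 466 and 380 genes for DMA, C646, DMA against C646, and DMA and C646 against starved, and 46 for both inhibitors in one direction.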

How the results depend on the processing

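Spike-in scaling, the transcript length offset and the block without solvent library 1 were chosen after the results were seen. Unless a reason is given, the cause was not tested.

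DESeq2 size factors and the stricter filter left every count of genes within 1.5 times its value. For genes called after stimulation (3704) a log2 fold change of at least 1 gave 1177, by construction, and leaving out 1 library 2269 to 3450. The block gave 5451. For DMA (267) the counts were 1064 by DESeq2, 455 without a filter, 31 with only the compared groups (fewer libraries), 1560 with the block, 471 with the block and no solvent library 1, 91 with spike-in scaling, 103 with the length offset, 87 with a log2 fold change of at least 1, and 1 (without DMA library 2) to 286 (without DMA library 1) leaving out 1 library. For C646 (185), in that order without the length offset, they were 864, 348, 71, 1199, 321, 100, 90 and 24 to 135. For DMA against C646 (441) they were 1016 by DESeq2, 140 with only the compared groups, 1498 with the block, 120 with spike-in scaling, 279 with the length offset, 185 with a log2 fold change of at least 1 and 180 to 316 leaving out 1 library. For DMA against starved (4109) spike-in scaling gave 6574, a log2 fold change of at least 1 gave 1438 and leaving out 1 library 3009 to 3480. For C646 against starved (3750) the last 2 were 1368 and 2514 to 3221.

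Genes changed by both inhibitors in one direction (23) were 196 by DESeq2, 57 without a filter, 311 with the block, 37 with the block and no solvent library 1, 13 with spike-in scaling, 10 with the length offset, 10 with a log2 fold change of at least 1 and 0 to 28 leaving out 1 library. The 0 came by edgeR without solvent library 1 or DMA library 2, with 425 and 624 genes at an unadjusted p under 0.05. Induced genes lower with DMA (54) numbered, in that order, 187, 83, 330, 98, 4, 25, 8 and 0 to 70, with 394 unadjusted beside the 0, which came without DMA library 2. Induced genes lower with C646 (35) numbered 189, 55, 286, 57, 11, 21, 14 and 1 to 31.

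For named genes, 105 of 169 calls ended in at least 1 alternative. DESeq2, the block and the stricter filter ended 0 calls, DESeq2 size factors 4, no filter 37, the length offset 36, the block without solvent library 1 19 and spike-in scaling 54. Besides the shift, spike-in scaling changed the SE. In DMA against solvent that of CDKN1A grew from 0.22 to 0.36 and that of BTG2 from 0.22 to 0.35, while that of FAM111B fell from 0.50 to 0.41. Besides the counts of genes above, the block added 30 calls of named genes and 2 list calls and ended 1 list call. With an estimated correlation as well, it ended the call of heat shock genes in DMA against C646 (0.11), and immediate early genes passed with DMA (0.012). After stimulation 6 genes reversed with spike-in scaling, which shifts every gene up by construction. They were EP300 (0.13), AJUBA (0.040), CDK4 (0.19, uncertain), TAF1D (0.11), BHLHE40 (0.081) and SLC39A10 (0.18).

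Of 40 list calls, an estimated correlation ended 38, spike-in scaling 4 and the stricter filter 2. Spike-in scaling added 5. Depth limits genes under 0.105 to 0.203 CPM, the level of 3 reads.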

Other observations

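No test of this part other than the comparisons of the report was planned, and the lists named here were chosen after their values were seen.

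Stress genes that fall when serum and glucose return were also lower when an inhibitor was present. Against starved cells, 23 of 27 amino acid response and ATF4 targets were lower and 1 higher with DMA (23 and 1 adjusted over the list alone), and 20 were lower and 1 higher with C646 (22 and 1). Of 19 chaperones and genes of the unfolded protein response, 17 were lower and 1 higher with DMA (18 and 1) and 14 were lower with C646 (18). With spike-in scaling the ATF4 medians of -1.27 and -1.17 became -0.37 and -0.40, and the chaperone and UPR medians of -1.02 and -1.04 became -0.21 and -0.28. Without DMA library 1, DMA library 2 or starved library 1 the count of 17 became 11, 9 and 10. Of 24 genes of sterol synthesis and uptake, 14 were lower with DMA (18 lower and 1 higher) and 16 with C646 (16). The sterol medians of -0.67 and -0.54 became 0.16 and 0.19 with spike-in scaling.

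Antioxidant, heat shock and p53 target genes were also counted against starved cells. The same 3 starved libraries enter both comparisons, so differences between the inhibitors here repeat the test of DMA against C646, and the counts were not compared by a test. Of 21 NRF2 antioxidant targets, 14 were higher with C646 (17 adjusted over the list alone, median 0.66, 1.46 with spike-in scaling) and 5 were lower with DMA (5, median -0.08, which became 0.75 with spike-in scaling). With the block 2 were higher and 6 lower with DMA. Without C646 library 1 or 3 or starved library 1 or 2 the count of 14 became 9, 8, 8 and 5, and without DMA library 1 or starved library 1 the count of 5 became 3. All 16 heat shock genes were higher with C646 (16, median 2.09, 2.77 with spike-in scaling) and 11 with DMA (13, median 0.90, 1.75 with spike-in scaling). Of 24 p53 targets, 13 were higher and 1 lower with DMA, and 14 higher and 1 lower with C646 (14 and 1 for both adjusted over the list alone). Of 22 mitotic genes, 6 were lower with C646 (10, and 12 over all genes with the block, median -0.59, which became 0.14 with spike-in scaling) and 1 was higher with DMA (1, with 2 lower without DMA library 1).

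Single DNA replication genes were also compared with starved cells. Of 30 DNA replication and E2F targets, 3 were lower and 1 higher with DMA (1 and 1 adjusted over the list alone) and 5 lower and 1 higher with C646 (5 and 1). The medians of -0.31 and -0.32 became 0.49 and 0.40 with spike-in scaling. Without DMA library 1, 2 or 3 or starved library 3 the count of 3 became 1, and without C646 library 1 the count of 5 became 2, as it became 3 without starved library 1, 2 or 3. Camera was not run against starved cells.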
